A study of Homo sapiens with 6 samples.

How the data were processed

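The deposited table holds estimated counts, reads per gene that need not be whole numbers, for 60669 genes in 6 libraries, 3 of RMUGS and 3 of RMUGS-R. Per the labels' protocols, total RNA was depleted of ribosomal RNA from 100 ng, made into libraries with a Kapa RNA HyperPrep kit and sequenced as paired reads of 150 bases on an Illumina NovaSeq instrument. The submitters' processing notes name kallisto 0.48.0, which assigns reads to transcripts by pseudoalignment, and the hg38 build. The transcript annotation, the step from transcripts to genes, the use of strand and any filter are not given in the sources used here. The deposited estimated counts are not scaled to depth or length, so a shift between long and short isoforms of a gene can move them. Kallisto splits reads that fit several transcripts, so values of near-identical paralogs and of overlapping or antisense genes are uncertain. The series' design text names DESeq2 and limma for the authors' own comparison, and both were run here as alternatives.

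Estimated counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr for the groups, which left 20675 genes, library sizes were scaled by TMM, and RMUGS-R was compared with RMUGS by edgeR's quasi-likelihood test with robust dispersions (edgeR 4.0.16, R 4.3.3). Calls were made at a Benjamini-Hochberg adjusted p under 0.05, and a second count required a log2 fold change of at least 1 in either direction. Every adjusted p of a gene comes from this fit unless another tool is named. Standard errors of log2 fold changes come from the same fit, CPM values use the TMM-scaled library sizes, and log2 CPM for lists used a prior count of 2. The common biological coefficient of variation was 6.82%. At an unadjusted p under 0.05 there were 6975 genes. A floor of 3 counts corresponds to 0.485 CPM in the smallest library, RMUGS replicate 1, and to 0.165 CPM in the largest, RMUGS replicate 3. Such floors cover counting error only, whereas SE and SD values include the spread between libraries.

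Gene lists, 32 in all with 743 distinct genes, each found in the table, were fixed before the data were examined, and so were the tests and most alternatives. Counts of list members refer to those that passed the filter on counts. Of 22 NF-kB and inflammatory genes 12 did, and of 20 mesenchymal genes 12. Each list was tested with camera (limma 3.58.1) on log2 CPM with a preset inter-gene correlation of 0.01, two-sided, adjusted over the 32 lists. With a correlation estimated per list 0 lists passed (smallest adjusted p 0.65), and 1, the NRF2 targets, had an unadjusted p under 0.05. Fry, which asks whether a list moves one way without comparing it with other genes, passed 15 lists, and 9 passed both camera and fry. The lists past camera and not past fry were replication fork, mitosis and both respiratory lists. Those past fry and not past camera were NAD metabolism (lower, fry adjusted p = 0.046), drug efflux (higher, 0.013), drug-metabolizing enzymes (lower, 0.017), the integrated stress response (higher, 0.017), mesenchymal genes (higher, 0.013) and nuclear-retained RNA (higher, 0.023). Fry's mixed test, for change in either direction, passed all 32.

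The genes named were chosen by a rule fixed beforehand. It took PARG, then the 10 largest rises and 10 largest falls among called genes with a mean log2 CPM of at least 3, no overlap between the lines and a symbol that is not a clone name or pseudogene. From each list with a called member it took up to 4 members by smallest adjusted p, with all members for ADP-ribose enzymes, and from the lists of other cell types and RNA quality the 4 most abundant. It gave 155 genes, and a small part of what the rules selected is not reported here. Members of a list and direction with 5 or fewer calls are named as well, which added 48 genes chosen after their values were seen.

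Replicates of a line were compared by a chi-square of their counts per gene, which lay between 2.45 and 4.32 for each of the 6 pairs, above the 1 that sampling noise alone gives, so no library was treated as a copy of another. Gene types and positions came from the GENCODE 29 annotation of hg38, which holds 20022 of the 20675 tested genes. It may not be the annotation the authors used. For the comparison by chromosome, expressed protein-coding genes had a mean log2 CPM of at least 1, and each gene's neighbourhood was the median log2 fold change of the 50 nearest such genes. Entering that median as an offset gave an alternative, added after the data were examined, that measures each gene relative to the genes around it. The offset was taken as known, so the error of the neighbours' median is not in the p-values behind those calls. Trends with GC content, length and abundance were fitted with mgcv 1.9.3. Length and GC content were those of each gene's longest annotated transcript, which need not be the one expressed.

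The scripts were tested on simulated counts drawn for 20129 genes kept in the simulation from the means, dispersions and library sizes of these libraries. With 200 genes changed, the test recovered 73.1% of those changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 4-fold, with the right sign in 100%, and 9.38% of its calls were unchanged genes. A list shifted by 0.3 on the log2 scale gave a camera adjusted p of 2.3e-18 and 0 other lists passed. Genes were drawn independently of each other, so the simulation could not test the preset correlation of camera. It also changed far fewer genes than were called in the data. The 200 changed genes included none of the least abundant ones, so the recovery rates do not cover those. A chromosome shifted by 0.3 was recovered at 0.30. Its shift fell to 0.00013 after the offset, which follows from how the offset is built, since it is taken from the same simulated genes. Shifts of part of a chromosome were not simulated. Alternatives were RLE scaling, library size alone, no filter beyond 1 count, a filter of CPM above 1 in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, no mitochondrial or ribosomal RNA genes, and the estimated correlation.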

Results

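The data are 6 RNA libraries of a mucinous ovarian cancer cell line, sequenced after ribosomal RNA depletion. RMUGS (RMUG-S) is an established line from a mucinous cystadenocarcinoma, an ovarian tumour whose cells resemble mucus-secreting epithelium, and 3 libraries came from the untreated parental line. The other 3 libraries came from RMUGS-R, a derivative selected by rising doses of an inhibitor of PARG, the hydrolase that removes poly-ADP-ribose chains from proteins. Selection took 4 months, RMUGS-R had an IC50 for growth about 10 times that of the parent, and its cells were kept free of the drug for 2 weeks before RNA was taken. The comparison therefore asks which transcripts differ between the resistant and the sensitive line in the absence of inhibitor. Total estimated counts were 6240528, 14204022 and 18400831 in RMUGS replicates 1, 2 and 3 and 12921154, 15463524 and 12629902 in RMUGS-R replicates 1, 2 and 3. The series calls the libraries triplicates without saying whether each came from a separate culture, so p-values measure the spread between these libraries, which may be technical. All 3 RMUGS-R libraries come from 1 derived line, so the comparison is between that line and its parent.

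The transcript of the drug's target, PARG, did not pass the test for a difference. PARG (ENSG00000227345.8, chromosome 10, 49818279 to 49970203 of hg38) stood at 27.6 ± 1.36 CPM (counts scaled to a common library size, mean ± SD, n = 3) in RMUGS and 29.4 ± 1.46 CPM in RMUGS-R. Its log2 fold change was 0.08 (SE 0.08, edgeR quasi-likelihood adjusted p = 0.53). Of the 15 measured enzymes that make, read or remove ADP-ribose, 4 passed the test, both over all genes and adjusted over the list alone. OARD1, which removes the terminal ADP-ribose from glutamate and aspartate, was higher (log2 fold change 0.40, SE 0.11), as was the DNA-damage-activated polymerase PARP2 (0.28, SE 0.08). The tankyrase TNKS2 (-0.20, SE 0.05) and the arginine-specific hydrolase ADPRH (-0.92, SE 0.27) were lower. PARP1, the main producer of the polymer after DNA damage, had a log2 fold change of -0.12 (adjusted p = 0.13), from 105 ± 8.10 to 96.6 ± 1.23 CPM. The other values that did not pass were 0.15 for HPF1, 0.16 for PARP3, 0.06 for ADPRS, -0.01 for TNKS, -0.18 for MACROD1, 0.08 for MACROD2, 0.61 for ENPP1, -0.08 for NUDT5 and -0.14 for NUDT16. The list did not pass camera (adjusted p = 0.97). The call of TNKS2 was lost without RMUGS replicate 3 (-0.18). That of PARP2 was lost without RMUGS replicate 2 (0.26), RMUGS-R replicate 1 (0.25) or RMUGS-R replicate 3 (0.25), and with DESeq2 (0.26). ADPRH lost its call without RMUGS replicate 1 (-0.76), RMUGS-R replicate 1 (-0.78) or RMUGS-R replicate 2 (-0.79), and OARD1 lost its call relative to the genes around it (0.11). In that comparison, which was chosen after the data were examined, PARP1 gained a call (-0.20).

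RMUGS-R differed from its parent at 5036 of 20675 tested genes, with 2759 higher and 2277 lower. Without RMUGS-R replicate 3 the balance turned, with 2132 higher and 2228 lower, as it did relative to neighbouring genes, with 1853 higher and 2012 lower. Most differences were small, and 544 genes differed at least 2-fold, 336 of them higher and 208 lower. The largest rises were in KRT17, a keratin of basal and stressed epithelium, TGM2, a protein cross-linking transglutaminase, and MGAM, an intestinal brush-border enzyme that digests starch. KRT17 (ENSG00000128422.17, chromosome 17, 41619441 to 41624842) rose 13.5-fold, from 3.58 ± 0.739 to 48.6 ± 8.14 CPM (SD, n = 3, adjusted p = 1.2e-09). TGM2 (ENSG00000198959.12, chromosome 20, 38127387 to 38166578) rose 11.7-fold and MGAM (ENSG00000257335.8, chromosome 7, 141907813 to 142106747) 10.4-fold. CGA, the shared alpha subunit of the glycoprotein hormones, CPE, a carboxypeptidase that processes peptide hormones, and EEF1A2, a tissue-restricted translation elongation factor, followed with log2 fold changes of 3.08, 3.01 and 2.75. The adhesion molecule L1CAM rose from 35.3 ± 3.26 to 224 ± 14.3 CPM (log2 fold change 2.67, SE 0.07). ANXA3, an annexin, and PSG5, a pregnancy-specific glycoprotein, were also among the 10 largest rises, at 2.51 and 2.47. KRT17 and PSG5 have near-identical relatives, and their values are uncertain to the extent that reads were split among them.

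The largest fall was in TAC3, which encodes neurokinin B and went from 16.4 ± 2.32 to 1.05 ± 0.107 CPM (log2 fold change -3.94, SE 0.19, adjusted p = 5.9e-14). MTUS2, a microtubule-associated protein, had a log2 fold change of -2.66. The retinaldehyde dehydrogenase ALDH1A1, the most abundant gene among the 10 largest falls, went from 152 ± 7.67 to 30.9 ± 1.90 CPM, 4.91-fold lower (ENSG00000165092.13, chromosome 9, 72900662 to 73080442). CLCA2 (-2.09), DAAM2 (-1.99, -2.39 to -1.76 with 1 library left out, a Wnt pathway regulator), CECR2 (-1.93, a chromatin remodelling subunit), the collagen chain COL4A4 (-1.87), NIBAN1 (-1.87), the Hedgehog transcription factor GLI2 (-1.87) and the GABA receptor subunit GABBR2 (-1.75) made up the rest. Each of these largest rises and falls had no overlap between the 3 libraries of one line and the 3 of the other, as the rule that chose them required. Over all tested genes 7645 (37.0%) showed no overlap, against 10% by chance for 3 libraries against 3. Library RMUGS replicate 1 had the fewest counts and stood apart on the second principal component, which held 19.9% of the variance, whereas the first (42.9%) separated the lines.

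**Figure D1:**
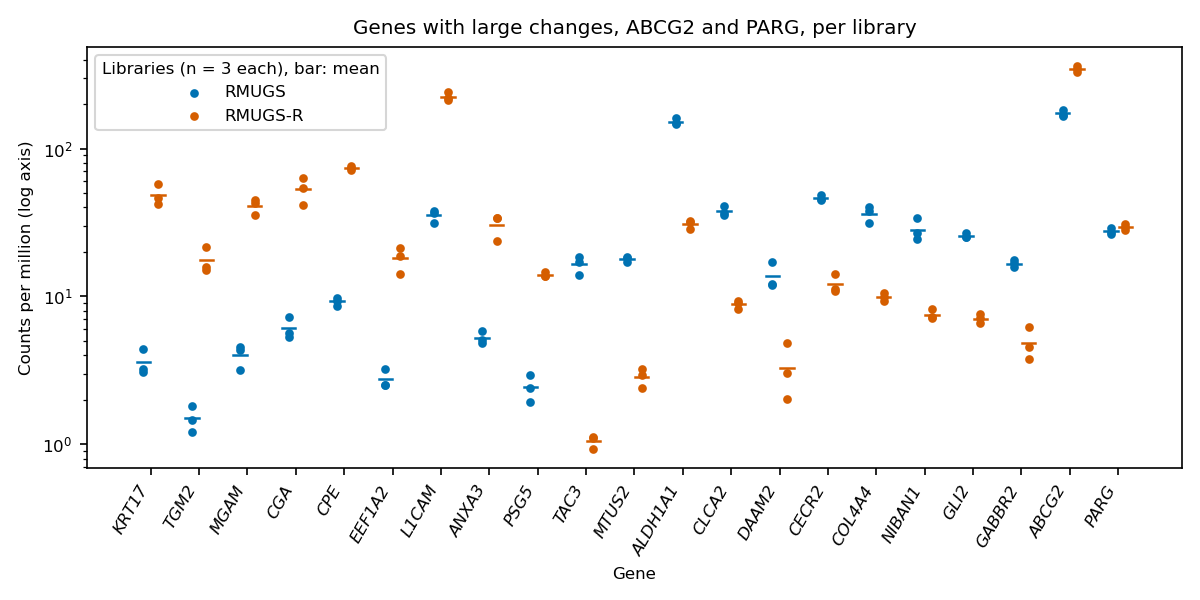
CPM on a log axis of genes with the largest changes named in the text, ABCG2 and PARG, with a point for each library and a bar for the mean of each line (n = 3). The libraries of the lines do not overlap for any gene shown but PARG, which lies at 27.6 CPM in RMUGS and 29.4 CPM in RMUGS-R.

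The drug exporter ABCG2, also called breast cancer resistance protein, doubled. It went from 173 ± 8.91 CPM in RMUGS to 345 ± 15.8 CPM in RMUGS-R (SD, n = 3), a log2 fold change of 1.00 (SE 0.05, edgeR adjusted p = 5.9e-14). ABCG2 (ENSG00000118777.12) lies on chromosome 4 at 88090264 to 88231322. Among 12 tested efflux genes, 4 were higher and 2 lower, and adjusted over the list alone 5 were higher and 2 lower. MVP, the major vault protein, rose (0.87), as did the exporters ABCC4 (0.57) and ABCC10 (0.40). ABCC1, which exports glutathione conjugates, fell (-0.25), and so did ABCC2 (-0.17). The list did not pass camera (adjusted p = 0.33). Drug-metabolizing enzymes moved in both directions, with 4 of 16 higher and 4 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.67). Besides ALDH1A1, the cytochrome CYP2S1 fell (-1.14), as did CYP1A2 (-0.42) and the glutathione transferase GSTM3 (-0.39). The aldehyde dehydrogenases ALDH1A3 (0.76) and ALDH3A1 (0.45), the acetyltransferase NAT1 (0.67) and the glutathione transferase GSTP1 (0.19) rose. Calls of ABCC2, ABCC10, CYP1A2, GSTM3 and NAT1 were lost when at least 1 library was left out, with lowest to highest log2 fold changes of -0.21 to -0.13, 0.32 to 0.48, -0.50 to -0.31, -0.50 to -0.29 and 0.53 to 0.75. That of CYP1A2 was lost when any of 5 libraries was left out, and that of GSTM3 when any of 4 was. Relative to the genes around them ABCC10 (0.045) and GSTM3 (-0.32) lost their calls and ALDH3A1 was at 0.27.

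Of 32 gene lists fixed beforehand, 13 passed camera with its preset correlation, 7 of them higher and 6 lower in RMUGS-R. Class I antigen presentation had the highest median of the 7 and the smallest camera p, although the NF-kB list had a higher mean (1.15 against 0.75) and, relative to neighbouring genes, a higher median (0.53 against 0.49). Of the 12 class I genes 11 rose (12 adjusted over the list alone), with a median log2 fold change of 0.74 and camera adjusted p = 1.7e-07 (adjusted p = 0.65 with an estimated correlation). The immunoproteasome subunit PSMB9 (1.34, SE 0.13), the peptide transporter subunits TAP2 (1.00) and TAP1 (0.91) and the loading factor TAPBP (0.79) led the list. TAPBP went from 196 ± 7.81 to 338 ± 18.1 CPM. These genes lie in the HLA region of chromosome 6, where 48 of 86 other tested genes were also higher and 0 lower, with a median of 0.36. Relative to the genes around them TAP2 was at 0.66, TAP1 at 0.58 and TAPBP at 0.50, each still called. The interferon response list had 10 of 26 genes higher and 1 lower (11 and 1 adjusted over the list alone, camera adjusted p = 0.0049, and adjusted p = 0.65 with an estimated correlation). The antiviral IFIT2 went from 3.43 ± 0.548 to 12.4 ± 1.5 CPM, and HERC6 rose by 0.83 on the log2 scale. SAMD9 rose by 0.37 and lost its call relative to the genes around it (-0.0096), where IFIT2 was at 1.74 and HERC6 at 0.58, both still called.

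Inflammatory, p53, MAPK and epithelial lists also passed camera upwards. Of 12 NF-kB and inflammatory genes 6 rose (7 adjusted over the list alone, camera adjusted p = 0.00091, and adjusted p = 0.65 with an estimated correlation). The adhesion receptor ICAM1 (0.895 ± 0.137 to 6.83 ± 1.96 CPM), the prostaglandin synthase PTGS2 (1.66 ± 0.496 to 5.78 ± 0.790 CPM) and NFKBIZ (log2 fold change 0.33, 108 ± 7.12 CPM in RMUGS) were among them. The p53 targets had 13 of 23 genes higher and 2 lower (14 and 4 adjusted over the list alone, camera adjusted p = 0.0049, and adjusted p = 0.65 with an estimated correlation). The cell cycle inhibitor CDKN1A rose from 104 ± 6.91 to 139 ± 7.37 CPM, the stress cytokine GDF15 from 24.9 ± 0.968 to 56.5 ± 9.64 CPM and PLK3 by 1.75 on the log2 scale, whereas TP53I3 (-0.73) and CCNG1 (-0.31) fell. MAPK output and immediate early genes had 12 of 21 members higher and 2 lower (13 and 2 adjusted over the list alone, camera adjusted p = 0.0055, and adjusted p = 0.65 with an estimated correlation). FOSL1 (1.82), ETV5 (0.74), PHLDA1 (0.73) and the phosphatase DUSP4 (0.58) rose, and DUSP6 and JUNB were lower at -0.21 each. The calls of DUSP6 and JUNB were lost when any of 5 and any of 3 libraries was left out, with ranges of -0.30 to -0.12 and -0.27 to -0.12. Relative to neighbouring genes CDKN1A was at 0.19, CCNG1 at -0.18 and JUNB at -0.33, each still called.

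The epithelial list had 9 of 18 genes higher and 3 lower (11 and 4 adjusted over the list alone, camera adjusted p = 0.043, and adjusted p = 0.71 with an estimated correlation). The cadherins CDH3 (1.10) and CDH1 (0.27) and the claudins CLDN7 (0.79) and CLDN4 (0.57) rose, and EPCAM (-0.18), ESRP1 (-0.16) and DSP (-0.14) fell, each of these 3 losing its call when at least 1 library was left out. The list's call itself was lost without RMUGS replicate 2 (adjusted p = 0.11), RMUGS replicate 3 (0.051) or RMUGS-R replicate 3 (0.23). It was lost as well with RLE scaling (0.058), with a replicate block (0.062) or without mitochondrial and ribosomal RNA genes (0.059). Over all its alternatives with the preset correlation its adjusted p ran from 0.0058 to 0.23. Relative to neighbouring genes the list lost its call (0.052), as did CLDN4 (0.14) and EPCAM (0.019), and CDH1 was at 0.17 and DSP at -0.40, both still called.

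The replication fork list passed camera upwards and the mitosis list downwards, and neither passed fry. Of 40 genes of the helicase, clamp, clamp loader and polymerases 17 rose and 0 fell (the same counts adjusted over the list alone, median 0.19, camera adjusted p = 7.0e-05, and adjusted p = 0.65 with an estimated correlation). The helicase subunits MCM7 (56.2 ± 6.49 to 90.9 ± 4.81 CPM), MCM5 (85.4 ± 6.13 to 126 ± 9.49 CPM) and MCM3 (101 ± 10.3 to 146 ± 5.63 CPM) and the clamp loader RFC1 (84.9 ± 1.29 to 114 ± 1.68 CPM) had the smallest adjusted p. Of the 17, 10 lie on chromosomes 4, 6, 7, 20 and 22, which hold 11 of the 40 members. The median log2 fold changes of these chromosomes were above 0, on chromosome 6 over part of its length. The 29 members on other chromosomes had a median of 0.12. Among all tested protein-coding genes 2483 of 13902 were higher. Relative to the genes around them MCM7 was at 0.22, MCM5 at 0.28, MCM3 at 0.22 and RFC1 at 0.17, each still called, against 0.68, 0.56, 0.52 and 0.42 without that correction. Fry, which tests whether the list moves one way, gave adjusted p = 0.053. The mitosis list had 9 of 25 genes lower and 1 higher (the same adjusted over the list alone, camera adjusted p = 0.011, fry adjusted p = 0.11, and adjusted p = 0.71 with an estimated correlation). The checkpoint kinases BUB1 (-0.30) and TTK (-0.36), the motor KIF20A (-0.25) and CENPF (-0.20) fell, and CCNA2 was higher (0.21), a call lost when any of 3 libraries was left out (0.15 to 0.27). BUB1 lies among lower genes of chromosome 2 and lost its call relative to them (-0.036), and CCNA2 lost its call in the same way (-0.071). The list lost its call without RMUGS replicate 2 (adjusted p = 0.11) or RMUGS-R replicate 2 (0.055).

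Cytosolic ribosomal protein genes fell almost as a block. Of 73 genes 57 were lower and 0 higher (60 and 2 adjusted over the list alone), with a median log2 fold change of -0.29, camera adjusted p = 1.9e-17 and adjusted p = 0.65 with an estimated correlation. RPL5 went from 528 ± 16.8 to 379 ± 19.1 CPM, RPL13A from 898 ± 31.9 to 672 ± 12 CPM and RPS2 from 707 ± 27.9 to 527 ± 10.1 CPM. Together these genes took 2.19% ± 0.072 of the counts in RMUGS and 1.79% ± 0.054 in RMUGS-R (SD, n = 3, exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). RN7SK, a nuclear RNA that restrains transcription elongation, rose from 0.782% ± 0.016 to 1.28% ± 0.060 of the counts (exact permutation p = 0.1), and RN7SL, the RNA of the signal recognition particle, was at 0.808% ± 0.024 and 0.963% ± 0.085 (exact permutation p = 0.1). Of the 10 nuclear-retained and structural RNAs listed as markers of RNA quality 4 were higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.29). These were RN7SK (0.71), RN7SL2 (0.32), RN7SL1 (0.21) and TUG1 (0.17). Calls of RN7SL1 and RN7SL2 were lost when at least 1 library was left out (0.15 to 0.28 and 0.26 to 0.40). Relative to neighbouring genes TUG1 lost its call (-0.023), and RN7SK was at 0.46 and RPL13A at -0.26, both still called. MALAT1 and NEAT1 had log2 fold changes of 0.08 (adjusted p = 0.20) and -0.23 (adjusted p = 0.59).

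**Figure D2:**
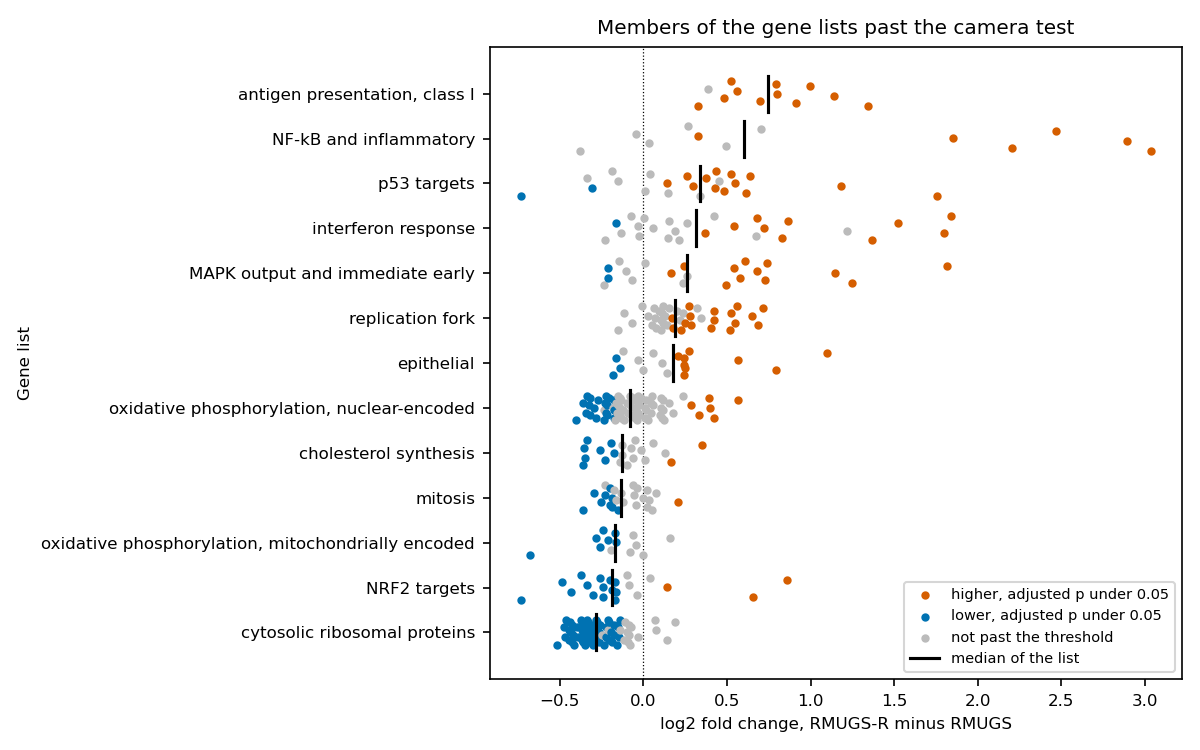
Log2 fold change, RMUGS-R minus RMUGS, of each tested member (points) of the 13 lists past camera, with the list's median as a black bar and colour for members past adjusted p of 0.05 (orange higher, blue lower, grey neither). The medians run from -0.29 for ribosomal proteins to 0.74 for class I antigen presentation.

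Lists of NRF2 targets, respiratory chain genes and cholesterol synthesis genes passed camera downwards, and neither respiratory list passed fry. Of 21 NRF2 targets 14 fell and 3 rose (15 and 3 adjusted over the list alone, camera adjusted p = 0.0013, and adjusted p = 0.65 with an estimated correlation, where the unadjusted p was 0.028). The ferritin light chain FTL went from 4443 ± 125 to 3169 ± 131 CPM, the pentose phosphate enzyme TKT from 1143 ± 62.8 to 884 ± 12.3 CPM and the aldo-keto reductase AKR1C1 by -0.73, which is uncertain because it has close paralogs. The cystine importer SLC7A11 went the other way, from 839 ± 29.4 to 1523 ± 63.0 CPM, as did HMOX1 (0.66) and TXNRD1 (0.14, lost without RMUGS replicate 2 at 0.12 or RMUGS-R replicate 3 at 0.072). Of 13 mitochondrially encoded respiratory genes 7 fell and 0 rose (8 and 0 adjusted over the list alone, camera adjusted p = 0.0096, fry adjusted p = 0.065, and adjusted p = 0.65 with an estimated correlation), led by MT-ND4L (-0.28), MT-ND2 (-0.24) and MT-ND3 (-0.68). Counts from the mitochondrial genome were 12% ± 0.769 of the total in RMUGS and 11.2% ± 0.503 in RMUGS-R (exact permutation p = 0.2). Of 76 nuclear respiratory genes 20 fell and 6 rose (the same adjusted over the list alone, camera adjusted p = 0.031, fry adjusted p = 0.20, and adjusted p = 0.71 with an estimated correlation). COX6B1 (-0.35), NDUFA10 (-0.32) and ATP5MC2 (-0.32) fell and ATP5MF rose (0.33). The list lost its call without RMUGS replicate 2 (adjusted p = 0.27) or RMUGS-R replicate 1 (0.22). Of 21 cholesterol synthesis genes 8 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.031, and adjusted p = 0.65 with an estimated correlation). SQLE (-0.34), HMGCS1 (-0.36) and SC5D (-0.36) fell, and CYP51A1 (0.35) and MSMO1 (0.17) rose, the last losing its call without RMUGS replicate 1 (0.13). The list lost its call without RMUGS replicate 3 (0.080) or RMUGS-R replicate 2 (0.12). Relative to neighbouring genes ATP5MF (-0.12), CYP51A1 (0.015), MSMO1 (-0.047) and HMOX1 (0.38) lost their calls, and NDUFA10 (-0.17) and SC5D (-0.22) kept theirs.

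No DNA repair list passed camera. Base excision and single-strand break repair had 1 of 23 genes higher and 2 lower (camera adjusted p = 0.97), translesion synthesis and gap filling 3 of 19 higher and 3 lower (0.67), homologous recombination and Fanconi anaemia 6 of 31 higher and 4 lower (0.50), and end joining with shieldin 4 of 15 higher and 2 lower (0.95). Adjusted over the list alone the counts were the same except for 5 lower in homologous recombination. The nuclease APEX2 (0.28) rose, and the scaffold XRCC1 (-0.27) and the glycosylase NEIL3 (-0.32) fell. In translesion synthesis the polymerase POLH (0.47), the sliding clamp PCNA (0.65) and the ligase RAD18 (0.22) were higher, and POLI (-0.36), REV1 (-0.21) and HLTF (-0.18) were lower. PCNA stood at 70.1 ± 13.2 CPM in RMUGS and 112 ± 7.90 CPM in RMUGS-R, and lost its call without RMUGS replicate 3 (0.63), RMUGS-R replicate 1 (0.67) or RMUGS-R replicate 3 (0.57). XRCC2 (0.42), RAD54L (0.40) and NBN (0.30) rose, whereas BARD1 (-0.26), MRE11 (-0.27), FANCE (-0.46) and FANCL (-0.24) fell. LIG4 (0.34), DCLRE1C (0.28), DYNLL1 (0.20) and XRCC6 (0.14) were higher, and XRCC5 (-0.27) and RIF1 (-0.15) lower. When at least 1 library was left out further calls were lost, given here with lowest to highest values. They were APEX2 (0.22 to 0.32), XRCC1 (-0.34 to -0.20), NEIL3 (-0.39 to -0.27), POLI (-0.42 to -0.32) and REV1 (-0.27 to -0.14). RAD18 (0.16 to 0.31), HLTF (-0.23 to -0.14), FANCE (-0.53 to -0.36), FANCL (-0.27 to -0.22) and LIG4 (0.30 to 0.41) were others. So were DCLRE1C (0.19 to 0.32), DYNLL1 (0.13 to 0.25), XRCC6 (0.085 to 0.18) and RIF1 (-0.20 to -0.13). FANCL lost its call when any of 5 libraries was left out, and RAD18, XRCC6 and DCLRE1C when any of 4 was. Relative to the genes around them calls were lost for POLH (0.093), PCNA (0.39), POLI (-0.28), REV1 (0.012), HLTF (-0.11), XRCC2 (0.017), BARD1 (0.0019), MRE11 (-0.072), FANCL (0.029), DYNLL1 (0.13), XRCC6 (-0.090), XRCC5 (-0.015) and RIF1 (0.064).

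Metabolic and stress lists outside the 13 held changes in both directions. NAD metabolism had 2 of 19 genes higher, NADK (0.43) and NAPRT (0.45), and 5 lower, QPRT (-0.49), NADSYN1 (-0.32), SIRT2 (-0.30), NMNAT3 (-0.28, lost without RMUGS replicate 3 at -0.24) and KYNU (-0.25), with the same counts adjusted over the list alone (camera adjusted p = 0.32). Glycolysis had 5 of 23 higher and 4 lower (6 and 4 adjusted over the list alone, 0.83). HK2 (0.89), PFKP (0.56), SLC16A3 (0.39), PFKFB3 (0.25) and SLC2A1 (0.21) were higher, and GPI (-0.32), SLC16A1 (-0.21), HK1 (-0.21) and LDHB (-0.20) lower. The hypoxia response had 3 of 13 higher and 4 lower (4 and 4 adjusted over the list alone, 0.85). EGLN3 (0.96), P4HA2 (0.90) and VEGFA (0.60) rose, and NDRG1 (-0.57), SLC2A3 (-0.51), KDM3A (-0.44) and ADM (-0.34) fell. Reactive oxygen enzymes had 4 of 14 higher and 3 lower (4 and 4 adjusted over the list alone, 0.67). GPX1 (0.68), GPX3 (0.60), GPX4 (0.48) and PRDX2 (0.45) were higher, and catalase (CAT, -0.49), GPX2 (-0.30) and PRDX6 (-0.20) lower. The integrated stress and unfolded protein response had 9 of 17 higher and 2 lower (the same adjusted over the list alone, 0.091), with ATF3 (0.98), PDIA4 (0.52) and XBP1 (0.46) among the former and PHGDH (-0.30) and MTHFD2 (-0.16) the latter. Calls of PFKFB3, HK1, LDHB, PRDX2 and MTHFD2 were lost when at least 1 library was left out. BCL2 family genes had 6 of 14 higher and 3 lower (7 and 4 adjusted over the list alone, 0.91). The 3 lower members, BMF (-1.22), BCL2L11 (-0.61) and PMAIP1 (-0.51), encode BH3-only proteins that promote apoptosis. Of the 6 higher members the rule named only the survival gene BCL2L1 (0.31), so the named genes do not give a direction for the list. Wnt targets had 2 of 9 higher and 1 lower (3 and 1 adjusted over the list alone, 0.83), namely CCND1 (0.49), LEF1 (1.06, lost when any of 4 libraries was left out, 0.90 to 1.3) and RNF43 (-0.38, lost without RMUGS replicate 3 at -0.30). Relative to neighbouring genes calls were lost for KYNU (-0.067), SIRT2 (-0.19), VEGFA (0.21), ADM (-0.21), PRDX2 (0.34), PDIA4 (0.13), MTHFD2 (0.023), BCL2L1 (0.12) and LEF1 (0.80). In that comparison GPI was at -0.17, KDM3A at -0.25, CAT at -0.33, BCL2L11 at -0.35 and XBP1 at 0.24, each still called. Signs differed between the median, the mean and the test for base excision repair (median 0.05, mean -0.00085, camera lower, fry higher), translesion synthesis (median -0.04, mean 0.0048, both tests lower), hypoxia (-0.02, 0.11, both lower) and reactive oxygen enzymes (-0.08, 0.0046, both lower). They also differed for the BCL2 family (0.16, 0.05, camera higher, fry lower) and the fibroblast, endothelial and blood list (0.08, 0.13, both lower).

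No list of identity markers of mucinous, mesenchymal or other cells passed camera in the main analysis, although the mesenchymal list passed fry as moving upwards (adjusted p = 0.013). With no filter on low counts the mesenchymal list (camera adjusted p = 0.044) and the serous and mesothelial list (0.033) passed. The mucin MUC1 rose from 46.0 ± 3.72 to 110 ± 12.2 CPM. Of 25 mucinous and gastrointestinal genes 13 passed the filter on counts, and 4 of these were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.67). Besides MUC1, CEACAM5 (0.77), MUC2 (1.62) and TFF1 (3.00) were higher, and MUC6 was lower (-0.80). MUC2 and TFF1 lay at 0.462 and 0.482 CPM in RMUGS, under the 0.485 CPM that 3 counts make in its smallest library. CEACAM5, MUC2 and MUC6 lost their calls when at least 1 library was left out (0.51 to 0.88, 1.15 to 2.31 and -1.14 to -0.53), and TFF1 kept its call (2.51 to 3.61). The call of MUC2 was lost when any of 4 libraries was left out. Of 12 mesenchymal genes 5 were higher and 3 lower (6 and 3 adjusted over the list alone, camera adjusted p = 0.28), with ITGA5 (1.46, 1.15 to 1.79 with 1 library left out), LOXL2 (1.10), FN1 (0.81) and CCN1 (0.47) among the higher and TWIST2 (-0.91), AXL (-0.46) and TGFBI (-0.42) the lower. TWIST2 and AXL lost their calls without RMUGS replicate 3 (-0.81 and -0.34), and AXL also without RMUGS-R replicate 3 (-0.35). Serous and mesothelial markers had 3 of 6 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.28). MUC16, which encodes CA125, was abundant in both lines at 4269 ± 355 and 3651 ± 183 CPM (-0.23, adjusted p = 0.0091), while MSLN (2.37, 1.87 to 2.79 with 1 library left out), CALB2 (1.00) and UPK3B (0.50) rose. Calls of MUC16 and CALB2 were lost when at least 1 library was left out (-0.29 to -0.18 and 0.79 to 1.16). Relative to neighbouring genes AXL (-0.29) and MUC6 (-0.80) lost their calls, and UPK3B was at 0.21, still called. Of 21 fibroblast, endothelial and blood markers 8 passed the filter on counts, and 2 were higher and 2 lower (the same adjusted over the list alone, camera adjusted p = 0.96). CDH5, the cadherin of endothelial junctions, rose 3.33-fold to 200.1 ± 28.2 CPM, while VWF, another endothelial gene, went from 6.21 ± 0.381 to 3.39 ± 0.286 CPM. POSTN (1.22, lost when any of 4 libraries was left out, 0.84 to 1.40) was higher, CSF1R (-1.28) was lower, and the collagen COL1A1 stood at 22 ± 2.58 and 24.3 ± 2.61 CPM (adjusted p = 0.27).

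Genes on the same chromosome were shifted together, a comparison chosen after the data were examined. Among 12384 expressed protein-coding genes the median log2 fold change was 0.33 on chromosome 7, 0.26 on chromosomes 4 and 22, 0.20 on chromosome 20 and 0.15 on chromosome 6. It was -0.20 on chromosome 2, -0.13 on chromosome 13 and -0.10 on chromosome 11. On chromosome 7, 353 of 576 genes were higher and 23 lower, and on chromosome 2, 34 of 844 were higher and 394 lower. Against 10000 random sets of as many genes, 16 of 23 chromosomes had an adjusted p under 0.05 (0.00019 for these 8, from a p of 1e-04, the smallest the draws can give). Genes are not independent replicates in that test. Median levels per library did not overlap between the lines on 20 of 23 chromosomes, where chance gives 10% of them. The shift was not even along some chromosomes. Medians of neighbouring genes were not adjusted for GC content, length or abundance, so they do not mark where a shift ends. On chromosome 7 the median of 51 neighbouring genes was 0.08 between 26152240 and 40099580 and reached 0.50 between 100064033 and 103099764, and on chromosome 6 it was 0.40 between 42963870 and 52529886 and -0.09 between 121435577 and 143340304 (hg38).

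**Figure D3:**
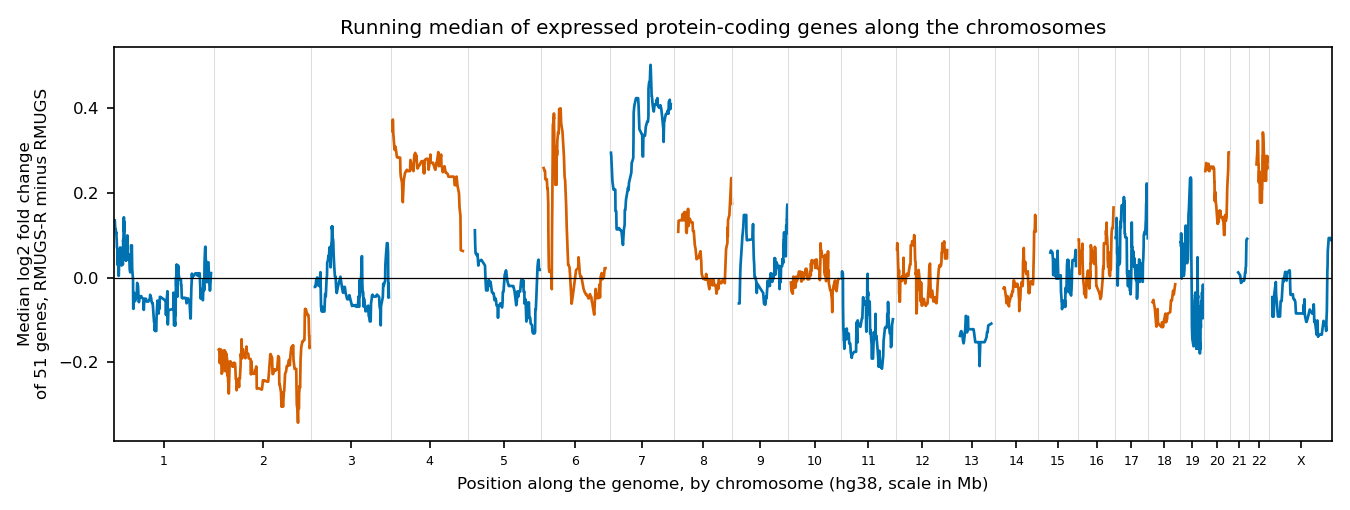
Median log2 fold change, RMUGS-R minus RMUGS, of 51 neighbouring expressed protein-coding genes along the chromosomes of hg38, with chromosomes in alternating colours and position to scale. Chromosomes 4, 7, 20 and 22 and part of chromosome 6 lie above 0. Chromosomes 2, 13 and 18 lie below it, down to -0.34 on chromosome 2.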

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

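The comparison relative to neighbouring genes was chosen after the data were examined, and the other alternatives before. The 5036 called genes became 3661 with DESeq2, which left 16243 genes with an adjusted p, and 5137 with limma-voom, with 3620 and 4934 shared with the 5036. The count was 4967 with RLE scaling, 4999 with library size alone, 4732 with no filter, 5058 with the stricter filter, 4952 without mitochondrial and ribosomal RNA genes, 3865 relative to neighbouring genes and 3697 to 4625 with 1 library left out. Except relative to neighbours, where 28 of 3169 shared genes changed sign, no shared gene changed sign. The 544 genes changed at least 2-fold became 382 with DESeq2, 465 relative to neighbours, 491 to 654 with 1 library left out and 684 with no filter. The median of all genes moved by at most 0.021 under any scaling or filter, but the share of called genes that were higher went from 54.8% to 50.5% with RLE, and it was 47.9% relative to neighbours and 48.9% without RMUGS-R replicate 3. The 13 lists became 0 with an estimated correlation, which was above the preset 0.01 for each of the 13, 10 to 14 with 1 library left out, 16 with no filter, 14 with limma-voom and 11 to 13 under the others. Of 32 lists 25 stayed on their side of the threshold under every alternative but the estimated correlation. The epithelial list also lost its call with RLE (adjusted p = 0.058), with the block (0.062), without mitochondrial and ribosomal RNA genes (0.059) and relative to neighbours (0.052). The integrated stress list gained a call with no filter (0.049), with limma-voom (0.021) and without RMUGS replicate 1 (0.050), and the mesenchymal (0.044) and serous and mesothelial (0.033) lists gained theirs with no filter.

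Replicate numbers did not pair the libraries. Same-numbered libraries had correlations of 0.043, -0.010 and 0.007 in their deviations from the group means, and RMUGS-R replicates 2 and 3 correlated more with another number. With the replicate block 4802 genes, 547 genes at least 2-fold and 12 lists passed. Of 187 named genes with a call, 119 kept it under every alternative that gave a value. Signs turned only relative to neighbouring genes, for REV1 (0.012), BARD1 (0.0019), RIF1 (0.064), FANCL (0.029), MTHFD2 (0.023), EPCAM (0.019), ATP5MF (-0.12), SAMD9 (-0.0096), XRCC6 (-0.090), CCNA2 (-0.071), MSMO1 (-0.047) and TUG1 (-0.023), because their own change was smaller than that of the genes around them.

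The 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5036 genes, 544 genes at least 2-fold and 13 lists, and 1 of 10 splits reached each of these. The other splits gave 0 genes, 0 genes and 2 to 7 lists. Camera with the preset correlation thus passed some lists for each of the other splits. Each of those splits put libraries of both lines into each group, so the difference between the lines raised the spread within groups. Their 0 genes are therefore not a measure of what chance gives. Depth limits low genes most in RMUGS replicate 1, where 16765 genes had at least 10 counts, against 22363 in RMUGS replicate 3.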

Other observations

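The test of read assignment among HLA genes was chosen after the result was seen, and so were the comparison relative to neighbouring genes and the search through gene families. Pregnancy-specific glycoprotein genes, normally made by the placenta, rose together in RMUGS-R. In an exploratory test of 253 families of at least 8 tested genes that share a symbol stem, 10 of 10 tested PSG genes were higher, with a median log2 fold change of 1.94 (camera adjusted p = 6.6e-09, 5.6e-11 relative to neighbouring genes). These genes are close copies side by side on chromosome 19, so reads shared among them make the 10 values far from independent. CGA, named for its large rise, stood at 52.9 ± 10.9 CPM in RMUGS-R against 6.10 ± 1.05 CPM in RMUGS. No list of placental genes was tested, so a joint rise of such genes beyond the PSG family is not shown. Replication fork genes had a median of 0.18 relative to the genes around them, against 0.19 without that correction, and their camera adjusted p was then 5.9e-05 with the preset correlation. Without the correction the list did not pass with an estimated correlation (adjusted p = 0.65) or with fry (0.053), so the support rests on the preset value. Leaving out 1 library gave 0.15 to 0.22, and the 29 members on other chromosomes than 4, 6, 7, 20 and 22 had a median of 0.12. ABCG2 had a log2 fold change of 0.75 relative to its neighbours, whose median was 0.25.

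Genes of chromosome 7 were higher together, and chromosomes 4, 20 and 22 and part of chromosome 6 moved likewise. After a smooth fit on abundance and on GC content and length of the longest annotated transcript, the median of chromosome 7 was 0.29. Without the shallow library RMUGS replicate 1 it was 0.33. These values argue against either such a trend or that library as the whole source of the shift of chromosome 7. The lower quartile of chromosome 7 lay 0.31 above that of the other chromosomes and the upper quartile 0.31 above, so the shift was not limited to a subset of strongly changed genes, although a stretch of 51 genes between 26152240 and 40099580 had a median of only 0.08. A candidate explanation is more copies of these chromosomes and fewer of chromosome 2 in a share or all of the RMUGS-R cells. It is a hypothesis, since no DNA was measured and only chromosome 7 was put through the checks above. Chromosomes 13 (median -0.13) and 11 (-0.10) were lower as well. Drug selection, growth from few cells and months of culture were not separated by the design, so they stay open as origins.

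Ribosomal protein genes were lower, with a median of -0.29. After the smooth fit the median was -0.31. Of 10000 lists matched on abundance and length 0 reached -0.29 (their lowest median was -0.16). Both used the longest annotated transcript of each gene, which need not be the one expressed. These values argue against a bias of abundance or annotated length, and a bias of short expressed transcripts stays open. Summed CPM of 1194 ribosomal protein pseudogenes changed by -45.9, from 417 to 372, while the genes fell from 21977 to 17974, so reads did not move to the pseudogenes. Without RMUGS replicate 1 the median was -0.31. Lower expression of these genes in RMUGS-R may be biological, as a hypothesis, and a difference in growth state or density at harvest was not tested.

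Class I antigen presentation genes rose by a median of 0.74, and the genes around them by 0.33. Relative to those neighbours the list's median was 0.49 (0.40 to 0.53 with 1 library left out), so the region's shift accounts for part of the rise and not for all of it. The 10 members on chromosome 6 had a mean of 0.80 against 0.40 for 86 other genes of the region (29722775 to 33299694, two-sided permutation p = 0.0013 with 100000 resamples, genes not being independent replicates). The 7 members without HLA in their symbol, whose sequences are not those of HLA genes, had a median of 0.80, so read assignment among HLA genes is not the whole source. An increase in RMUGS-R beyond the region's shift may be biological, as a hypothesis, and whether it goes back to inhibitor exposure or to selection was not tested.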
